A study of Mus musculus with 40 samples.

How the data were processed

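Genomic DNA of 40 mouse samples in 10 groups of 4 had been digested with MspI and sequenced after bisulfite treatment, per the labels' protocols. Per the submitters' processing notes, Trim Galore 0.4.5 and Bismark 0.20.0 were used with the build GRCm38, also called mm10. Coverage minimum and merging of strands are not given in the sources used here. The authors deposited a fraction or beta value per CpG site and sample, between 0 and 1, for 16454349 sites on chromosomes 1 to 19. No read depth stood beside the values, so no coverage filter, interval or count model could be applied, and the precision of a single site is unknown. In every library most values were exactly 0 or 1. Groups, ages and replicate numbers came from the sample titles and characteristics. The tissue was thymus in 36 libraries and spleen in the 4 Lmo2 T-ALL libraries, although the extraction text names thymus for all.

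Sites with a value in at least 3 of 4 samples of each of the 10 groups were kept (811670, of which 579152 had a value in all 40). No genome was used here, so CpG islands were replaced, as planned before the data were examined, by CpG-dense clusters: runs of at least 10 kept sites with gaps of at most 100 bases. Of these, 16971 with a value in every sample were tested and 293 were left out. They had a median of 18 sites over 273 bases and held 374807 sites. Shores were the 74276 kept sites within 2000 bases of a cluster, and open sea the remaining 362587. Gene positions came from a RefSeq table of GRCm38.p6, which gives no strand. In place of the planned promoters, a gene window was therefore taken from 1000 bases outside to 500 bases inside the gene end with more kept sites, with at least 5 sites. Such a window may lie at the 3′ end of the gene or at the promoter of a neighbour, and no exon or UTR is stated. There were 13698 windows, 11182 of them at protein coding genes.

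Cluster and window means were transformed as M = log2((beta + 0.01)/(1 - beta + 0.01)) and tested with limma 3.58.1 in R 4.3.3, with only the groups compared in the fit, no covariate, and Benjamini-Hochberg adjustment. A feature was called at an adjusted p under 0.05 and a difference of at least 10 percentage points. "Rose" and "fell" refer to such calls. Differences of differences were contrasts in a fit of 4 groups. Simulated rises of 0.15 and 0.3 in beta, over 16971 clusters, were recovered at 91 and 99 of 100 clusters with the spread of Pten KO against WT thymi, with 2 false calls. With the spread of Lmo2 T-ALL against TG thymi of 24 weeks, 66 and 76 of 100 were recovered, with 4 false calls. Spread was drawn independently for each cluster, and the rises were put in randomly picked clusters. Recovery is therefore not known for clusters that vary widely, or together, between the T-ALL libraries.

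Means per sample were compared by exact two-sided permutation tests over the 70 splits of 4 against 4, whose smallest p is 0.0286. Values were adjusted over the 30 tests of contrasts and contexts, and over the 10 tests of the share that gained. A first run had pooled these 40 tests in 1 family by mistake, which put the smallest adjusted p at 0.0497 for means and shares alike, and it was replaced by the planned families. For a difference of differences, the later group's values minus the mean of its own reference were permuted between the arms, which leaves out the error of the reference means and was settled after the results of other tests were known. The share that gained is the percent of clusters with a mean under 10% over the 8 WT samples of 8 weeks that reached 20% in a sample. That selection lowers the values of those 8 samples a little. Relations with age used 100000 randomly drawn permutations, so their smallest p-values are estimates with a sampling error. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.

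The 17 gene lists were fixed at that time too, as was the rule for named genes: per contrast the 10 largest rises and 5 largest falls among called windows whose groups do not overlap (without that rule for differences of differences), up to 4 called members per list, and Pten and Lmo2 where measured. List means were tested by exact permutation, adjusted over 136 tests, of which none passed (smallest adjusted p = 0.0762). That value stands for every list at the smallest exact p, however large its difference. Camera was run with an estimated correlation. With a preset correlation of 0.01 a further 25 list tests passed 0.05, and no call was lost. Alternatives covered the offset, the scale, the site filter, the size of difference, cluster definition, samples in the fit, a replicate block and each replicate left out. The closing section names those that could not be run.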

Results

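DNA methylation was measured by reduced representation bisulfite sequencing, which reads CpG sites near MspI cut sites, in 40 libraries from 2 mouse models of T-cell acute lymphoblastic leukemia (T-ALL). In the first model, Lck-Cre deletes Pten, a phosphatase that restrains PI3K signalling, in thymocytes. In the second, a CD2-Lmo2 transgene drives Lmo2, a transcriptional cofactor of blood stem cells and a T-ALL oncogene. The Pten model gave 3 groups of 4 libraries: wild-type (WT) and knockout (KO) thymus of 8 weeks and KO T-ALL. The Lmo2 model gave 7 groups of 4: WT and transgenic (TG) thymus of 8, 16 and 24 weeks and TG T-ALL, whose tissue the labels give as spleen. A value was listed at 2584950 to 4507415 sites in the libraries of the Pten model, at 1367423 to 1921827 in the premalignant libraries of the Lmo2 model and at 3975403 to 4949547 in the Lmo2 T-ALL libraries. The read depth behind each value is unknown, since only fractions were used. The labels do not say that the replicates came from separate animals, so each p-value measures the spread between these samples, which may be technical. An exact permutation p of 0.0286 is the smallest that 4 samples against 4 can give, two-sided, and is reached when all 4 samples of one group lie above all 4 of the other. No larger difference can lower it. Its adjusted value therefore depends on how many tests of the same family reach it, and not on the size of the difference. All levels are percent methylation, given as mean ± SD with n = 4, and positions are on GRCm38.

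**Figure D1:**
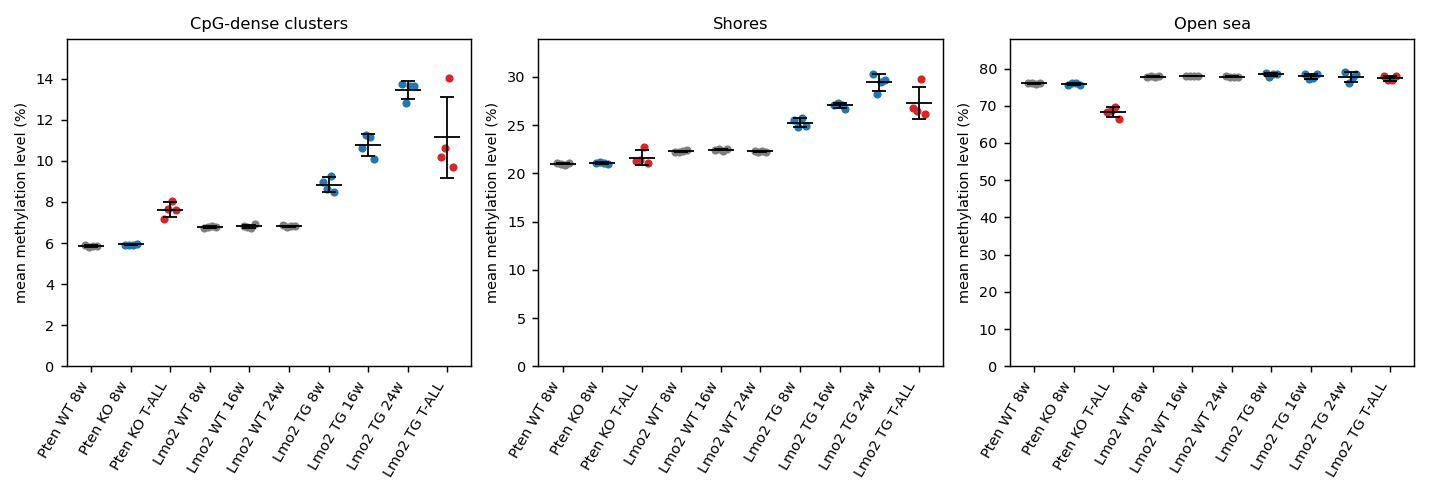
Mean methylation level in percent of CpG-dense clusters, of shores and of open sea for each of the 40 libraries by group, each axis starting at 0. Points are libraries in grey (WT), blue (premalignant KO or TG) and red (T-ALL), the long tick is the mean and bars are SD (n = 4), with clusters at 8.84% and 13.5% in TG thymi of 8 and 24 weeks and open sea at 68.2% in Pten KO T-ALL.

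Loss of Pten before leukemia was examined in KO against WT thymi of 8 weeks. No CpG-dense cluster and no gene window was called in either direction, and no member of any of the 17 gene lists was called. The window at Pten itself (chromosome 19, 32756577 to 32758077, 63 sites) held 0.308% ± 0.441 against 0.22% ± 0.316 in WT, a value that does not test the deletion. Clusters averaged 5.93% ± 0.0264 in KO and 5.85% ± 0.0308 in WT, a difference of 0.0768 percentage points. Developmental transcription factors averaged 4.61% ± 0.128 against 4.46% ± 0.071 and housekeeping genes 3.23% ± 0.138 against 3.13% ± 0.0943. By limma, 934 of 16971 clusters had an unadjusted p under 0.05, and a fit of all 40 samples also called 0. The exact permutation p of the cluster mean was 0.0286 and 0.0536 after adjustment, so the small difference did not pass. Over the 2732 clusters chosen in Lmo2 T-ALL, described below, KO stood at 7.29% ± 0.222 and WT at 6.86% ± 0.069 (exact permutation p = 0.0286, also adjusted over 8 tests). The share of clusters unmethylated at baseline that reached 20% or more was 0.032% ± 0.0101 in KO and 0.0185% ± 0.0208 in WT (exact permutation p = 0.371, also adjusted over 10 tests).

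Pten KO T-ALL was set against KO thymi of 8 weeks to ask what changes with leukemia in this model. No age was given for any T-ALL library, so leukemia and age cannot be told apart here. Methylation rose at 793 clusters and fell at 125 of 16971, and at gene windows 485 rose and 172 fell. The window of Col16a1, a collagen gene (chromosome 4, 130046817 to 130048317, 11 sites), stood at 68.6% ± 11.9 against 3.57% ± 3.69 (adjusted p = 0.00298). That of Cdo1, cysteine dioxygenase (chromosome 18, 46728002 to 46729502, 27 sites), stood at 73.4% ± 16.4 against 15.7% ± 3.66 (adjusted p = 0.00658). C2cd4d held 94.2% ± 8.35 against 10.2% ± 6.5 (adjusted p = 0.0062), and Cbfa2t3, a transcriptional corepressor of blood progenitors, 60.4% ± 14.9 against 5.41% ± 5.43 (adjusted p = 0.013). Scamp3, Naprt, Mansc4, Tctn2, Grb7 and Cul9 were the other windows among the 10 largest rises, with T-ALL means from 55.7% in Cul9 to 83.4% in Tctn2. Among the falls, Lexm held 7.13% ± 3.43 against 60.1% ± 8.12 (adjusted p = 0.00189) and Rhd, a red cell antigen gene, 45.4% ± 10.5 against 84.5% ± 1.91 (adjusted p = 0.00323), with Igflr1, Xirp1 and Leng9 also among the 5 largest.

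Of 116 measured developmental transcription factors, which are typical Polycomb targets, 9 rose and none fell (10 rose when adjusted over the list alone). Gbx2 stood at 36.1% ± 9.98 against 7.13% ± 0.966, Irx6 at 27.3% ± 8.41 against 5.33% ± 2.28, Msx2 at 22.1% ± 4.33 against 2.87% ± 0.759 and Alx1 at 23.7% ± 8.37 against 6.23% ± 0.596. Of 36 genes of the Wnt, BMP and hedgehog pathways, mostly ligands and secreted inhibitors, 5 rose (6 adjusted over the list alone), among them Bmp3 with 39.4% ± 10.4 against 10.9% ± 3.38 and Sfrp1, a secreted Wnt inhibitor, with 26% ± 10.1 against 2.86% ± 1.51. Gli3, a transcription factor of the hedgehog pathway, and Sfrp4 of this list rose too, Sfrp4 to 16.3% ± 6.8. Of 27 T-ALL oncogenes and progenitor genes Kit, a stem cell factor receptor, rose with 19% ± 7.5 against 0.113% ± 0.226 and Tal2 with 12.5% ± 6.01 against 0.997% ± 1.25 (3 rose and 1 fell when adjusted over the list alone). Nptx2 and Sox11, from the genes of published age clocks, rose to 47% ± 7.24 and 24.4% ± 13.4 (2 rose and 1 fell when adjusted over the list alone). Of 3 measured erythroid and megakaryocyte markers 1, Pf4, rose, and of 26 germline genes 1, Fkbp6, fell. None of 31 tumour suppressors, 30 Hox genes and 22 housekeeping genes was called (1 Hox gene fell when adjusted over the list alone), and the Pten window stayed at 0.0971% ± 0.0962. With an estimated correlation, camera gave adjusted p = 0.053 for the developmental factors, adjusted p = 0.0602 for the Wnt, BMP and hedgehog list and adjusted p = 0.0602 for the T-ALL oncogenes, so none of these lists passed.

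Cluster means were 7.63% ± 0.356 in Pten KO T-ALL and 5.93% ± 0.0264 in KO thymi, while open sea was at 68.2% ± 1.33 and 75.8% ± 0.261. Both had an exact permutation p of 0.0286, the smallest possible, and 0.0536 after adjustment over 30 tests. That does not pass 0.05, and no larger difference could have lowered it. The share of clusters unmethylated at baseline that reached 20% or more was 3.58% ± 0.803 in T-ALL and 0.032% ± 0.0101 in KO thymi (exact permutation p = 0.0286, 0.0408 adjusted). The count of falls was 80 without T-ALL replicate 4, and 70, 72 and 80 without KO replicates 2, 3 and 4. On untransformed values 476 rose and 82 fell, and with an offset of 0.001 the falls numbered 76.

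The Lmo2 transgene was compared with WT at each age. At 8 weeks methylation rose at 868 clusters and fell at 55 in TG thymi, and 558 gene windows rose and 36 fell. Eci1, an enzyme of fatty acid oxidation (chromosome 17, 24425683 to 24427183, 29 sites), held 72.8% ± 13 against 1.18% ± 0.723 (adjusted p = 0.00183). Cmya5 held 71.7% ± 15.4 against 2.14% ± 1.52 (adjusted p = 0.00336), Traf1, an adaptor of TNF receptors, 85.9% ± 7.53 against 14.8% ± 8.84 (adjusted p = 0.00365) and Fes, a tyrosine kinase, 85.1% ± 2.5 against 16.7% ± 2.28 (adjusted p = 0.000367). Col16a1 and Cdo1 stood at 70.9% ± 16.5 and 84.3% ± 8.77 in TG, with Abi3, Rsph1, Naprt and Slc12a9 also among the 10 largest rises. Lexm fell (10.6% ± 10.7 against 65% ± 7.76), as did Hoxb6 (38.6% ± 16.4 against 88.8% ± 4.16) and Hoxa5 (40% ± 17.2 against 82.2% ± 2.48), with Zfp119b and Fam166b also among the 5 largest falls.

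Among the lists at 8 weeks, 5 of 116 developmental factors rose (9 adjusted over the list alone), a share near that of 558 among all 13698 windows. Tbx4 stood at 92.7% ± 6.55 against 45.4% ± 4.24 and Irx1 at 15% ± 4.22 against 2.51% ± 1.34. Of 30 Hox genes 2 rose, Hoxa4 and Hoxd1, and the 2 named above fell (2 and 3 adjusted over the list alone), and the list's median difference was positive while its mean was negative. Of 36 Wnt, BMP and hedgehog genes 3 rose, Bmp3, Sfrp1 and Dkk2 (4 adjusted over the list alone), and of 18 age clock genes 4 rose, Hsf4 (82.3% ± 10.3 against 39.6% ± 5.08), Sox11, Nptx2 and Otud7a (5 adjusted over the list alone). Camera called the developmental, the Wnt, BMP and hedgehog and the age clock lists with an estimated correlation at 8 weeks (adjusted p = 0.017, 0.0198 and 0.0198) and at 16 weeks (adjusted p = 0.0196, 0.019 and 0.019). Of the few measured marker windows Spib of the B cell list, Pf4 of the erythroid and megakaryocyte list and Krt18 of the stromal list rose. None of 22 housekeeping genes was called. The cluster mean was 8.84% ± 0.357 in TG and 6.79% ± 0.0331 in WT, with an exact permutation p of 0.0286 and 0.0536 after adjustment. The share of baseline-unmethylated clusters that gained was 3.74% ± 1.03 against 0.0808% ± 0.0182 (exact permutation p = 0.0286, 0.0408 adjusted). With an offset of 0.001, 335 clusters rose and 16 fell. The falls numbered 36, 35 and 36 without WT replicates 1, 2 and 3.

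At 16 weeks 2353 clusters rose and 62 fell in TG against WT, with 1388 gene windows higher and 57 lower. Naprt, an enzyme of NAD synthesis (chromosome 15, 75893981 to 75895481, 8 sites), stood at 87.3% ± 6.33 against 3.65% ± 4.29 (adjusted p = 0.00074), Lgals3, galectin 3, at 83.8% ± 10.8 against 4.6% ± 1.56 (adjusted p = 0.000316) and Gal, the neuropeptide galanin, at 80.4% ± 8.1 against 6.64% ± 2.67 (adjusted p = 0.000265). Cdo1 had reached 96% ± 2.02 and Eci1 82.3% ± 20.1, with Mchr1, Rsph1, Slc12a9, Fam83f and Traf1 completing the 10 largest rises. Lexm, Emp3, Hoxb6, Hoxa5 and Fam166b were the largest falls, Emp3 with 20.6% ± 6.05 against 70.2% ± 8.86. Of 116 developmental factors 44 rose (45 adjusted over the list alone), of 30 Hox genes 10 rose and 2 fell (11 and 2 adjusted over the list alone), of 36 Wnt, BMP and hedgehog genes 11 rose (11) and of 18 age clock genes 7 (9). The Hox list had an adjusted p = 0.12 with an estimated correlation. Irx1 stood at 40.6% ± 7.66 against 5.57% ± 0.986, Bmp2 at 28.2% ± 4.43 against 2.1% ± 0.991, Sfrp1 at 42.5% ± 6.81 against 3.57% ± 1.83 and Sox11 at 42.4% ± 8.51 against 5.39% ± 1.75. Of 27 T-ALL oncogenes and progenitor genes 4 rose, Cd34, Hoxa11, Nkx2-2 and Tlx3 (adjusted p = 0.084 with an estimated correlation), and of 22 imprinted genes 2, Nap1l5 and Rasgrf1. The imprinted share was near that of 1388 among all 13698 windows. S1pr1, Pax5 and Pf4 were the marker windows that rose. The cluster mean was 10.8% ± 0.538 against 6.81% ± 0.0838 and the share that gained 9.05% ± 1.61 against 0.146% ± 0.043. Both had an exact permutation p of 0.0286, adjusted to 0.0536 for the mean and 0.0408 for the share. The falls numbered 39 with an offset of 0.001.

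At 24 weeks the transgene went with 3471 clusters higher and 48 lower, 20.5% and 0.28% of those tested, and with 2010 gene windows higher and 54 lower. Eci1 held 93.5% ± 3.67 against 1.98% ± 0.483 (adjusted p = 1.53e-05), Cmya5 91.9% ± 11.5 against 0.703% ± 1.41 (adjusted p = 0.000207), Col16a1 93.3% ± 2.75 against 2.74% ± 1.45 (adjusted p = 1.64e-05) and Cdo1 97.6% ± 1.01 against 18.2% ± 2.35 (adjusted p = 1.53e-05). Naaladl2 (chromosome 3, 25143649 to 25145149, 34 sites) stood at 86% ± 0.597 against 6.12% ± 2.72 and Mchr1, a receptor of melanin-concentrating hormone, at 93.2% ± 3.06 against 8.78% ± 1.5. Naprt, Gal, Lgals3 and Acot11 also stood among the 10 largest rises. Lexm fell to 1.97% ± 1.75 from 71.2% ± 9.33, and Slpi, a protease inhibitor, held 38.1% ± 7.68 against 84.9% ± 6.69, with Rhd, Srsf1 and Gdpd1 also among the 5 largest falls.

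**Figure D2:**
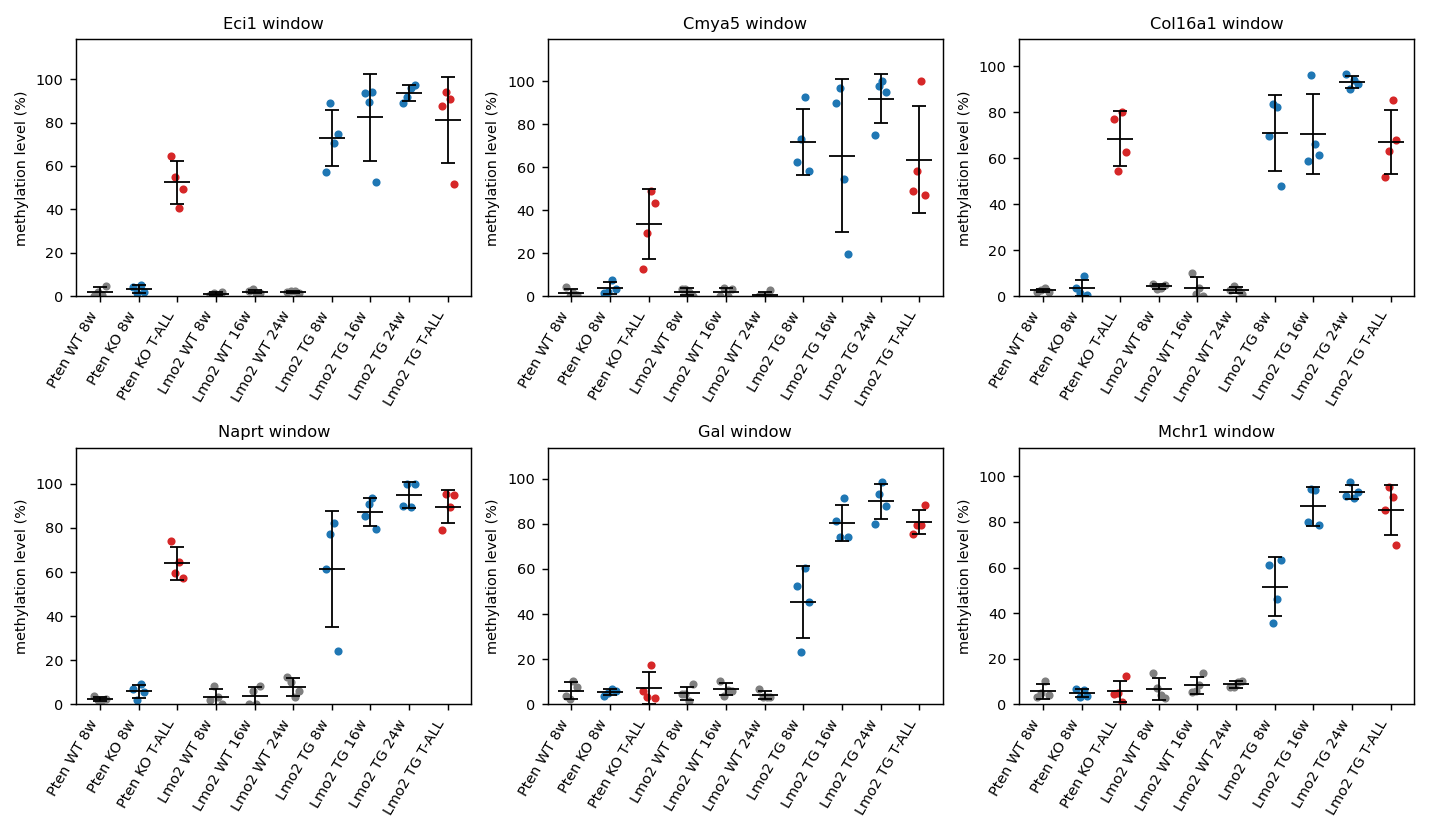
Methylation level in percent of the gene windows with the 6 largest rises between TG and WT thymi of 24 weeks, for each library by group. Points are libraries, the long tick is the mean and bars are SD (n = 4), and the Eci1 window averaged 93.5% in TG and 1.98% in WT thymi of 24 weeks.

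Called genes were counted by list at 24 weeks as well. Of 116 developmental transcription factors 78 rose and none fell (84 adjusted over the list alone), with Irx1 at 68.1% ± 6.2 against 4.11% ± 2.49, Foxg1, a forebrain factor, at 46.4% ± 10.5 against 3.32% ± 2.94 and Isl1 at 44.1% ± 15.3 against 4.42% ± 0.451. Of 30 Hox genes 15 rose (16 adjusted over the list alone), with Hoxd1 at 47.2% ± 6.78 against 6.56% ± 1.36 and Hoxa4 at 38.5% ± 10.7 against 1.83% ± 1.03. Of 36 Wnt, BMP and hedgehog genes 19 rose (20 adjusted over the list alone), with Bmp2 at 62.5% ± 2.38 against 1.91% ± 0.725, Gli3 at 52.5% ± 7.37 against 3.3% ± 1.09 and Sfrp1 at 51.2% ± 19 against 5.87% ± 1.95. Of 18 age clock genes 12 rose (12 adjusted over the list alone), with Sox11 at 61.5% ± 8.32 against 6.45% ± 1.32, Nptx2 at 62.6% ± 8.35 against 9.73% ± 0.986 and Otud7a at 52% ± 6.64 against 1.96% ± 1. These 4 lists were called by camera with an estimated correlation, with adjusted p = 0.00433, 0.011, 0.00612 and 0.00671 in that order.

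The other lists at 24 weeks held fewer called genes each. Of 27 T-ALL oncogenes and progenitor genes 6 rose (8 adjusted over the list alone), with Meis1, a Hox cofactor, at 32.9% ± 6.37 against 1.5% ± 0.511 and Tlx3 at 28.6% ± 3.28 against 4.9% ± 1.42. Camera gave this list an adjusted p of 0.0751 with an estimated correlation. Of 22 imprinted genes 6 rose (10 adjusted over the list alone), with Peg12 at 66% ± 10.4 against 21.3% ± 5.92 and Mkrn3 at 65.3% ± 12 against 29.2% ± 7.66, with an adjusted p of 0.0751 in the same test. Of 23 clustered protocadherins 3 rose (6 adjusted over the list alone, camera adjusted p = 0.4 with an estimated correlation), a share near that of 2010 among all 13698 windows. Of 31 tumour suppressors Trp73 rose (19.8% ± 5.82 against 2.8% ± 1.21) and Ikzf1, a lymphoid factor, fell (1.04% ± 1.2 against 17.8% ± 5.59). S1pr1 and Eomes of 4 effector windows, Spib and Ebf1 of 3 B cell windows, Fcgr3 of 7 myeloid windows and Krt18 and Prrx1 of 7 stromal windows rose, the stromal list with a positive mean and a negative median difference. None of 10 T lineage genes, 30 genes of the methylation and Polycomb machinery, 26 germline genes and 22 housekeeping genes was called, the last with 3.58% ± 0.226 against 3.98% ± 0.0966. The Pten window stood at 0.468% ± 0.16 against 0.776% ± 0.53, and no window at Lmo2 was measured.

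The cluster mean at 24 weeks was 13.5% ± 0.437 in TG and 6.83% ± 0.0281 in WT, and shores stood at 29.4% ± 0.858 and 22.3% ± 0.0576, each with an exact permutation p of 0.0286 and 0.0536 adjusted. Open sea was at 77.8% ± 1.35 and 77.8% ± 0.0897 (exact permutation p = 1). The share of baseline-unmethylated clusters that gained was 15.4% ± 0.962 in TG and 0.153% ± 0.0715 in WT (exact permutation p = 0.0286, 0.0408 adjusted).

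**Figure D3:**
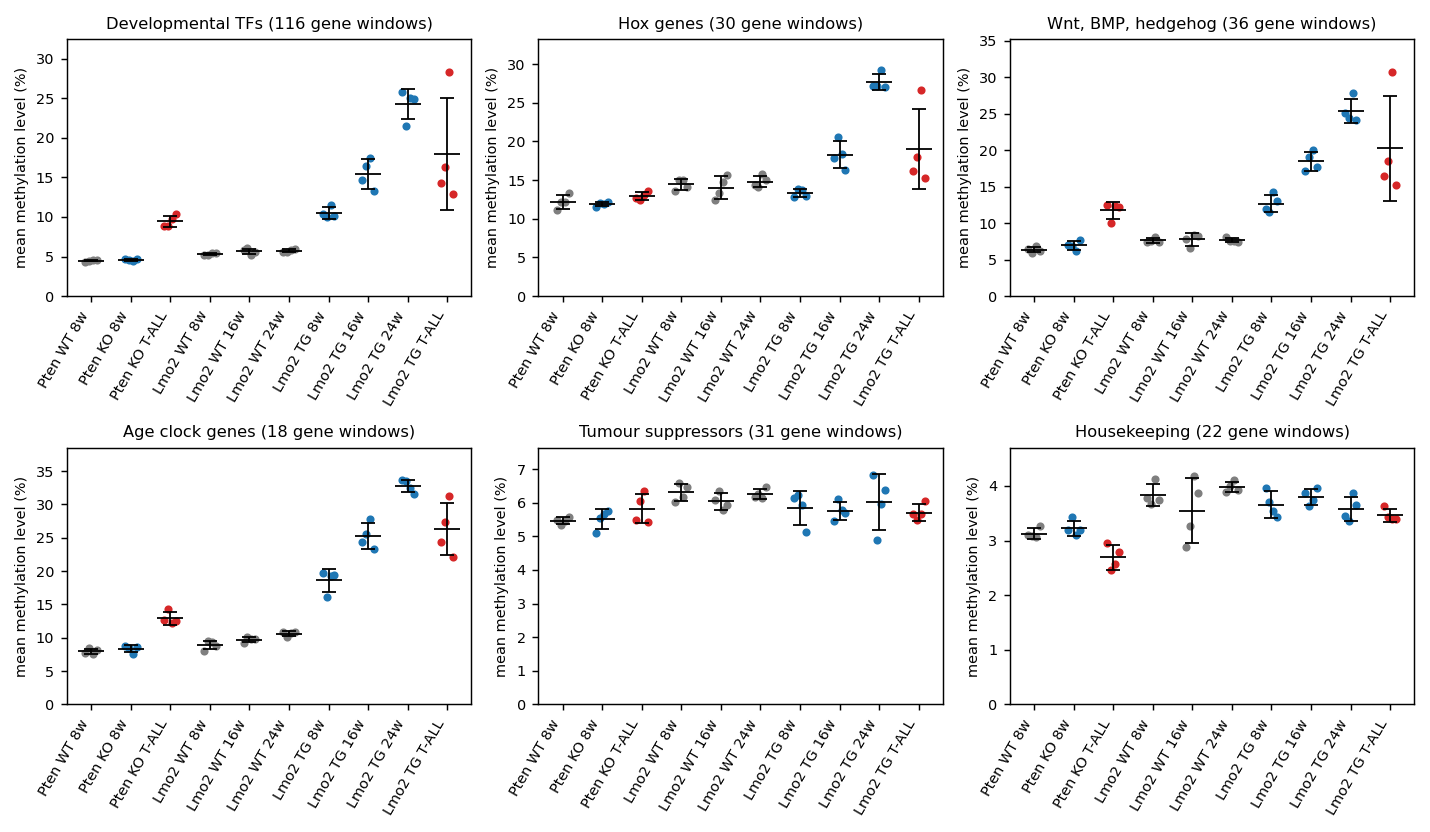
Mean methylation level in percent over the measured gene windows of 6 gene lists, for each library by group, each axis starting at 0. Points are libraries, the long tick is the mean and bars are SD (n = 4), and developmental transcription factors averaged 24.3% in TG and 5.74% in WT thymi of 24 weeks, and housekeeping genes 3.58% and 3.98%.

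Age without the transgene was examined in WT thymi of 24 against 8 weeks. No cluster and no gene window was called by limma, with 931 clusters at an unadjusted p under 0.05 and 0 calls in a fit of all 40 samples. Irx1, Bmp2 and Meis1 held 4.11% ± 2.49, 1.91% ± 0.725 and 1.5% ± 0.511 at 24 weeks and 2.51% ± 1.34, 2.46% ± 1.06 and 1.5% ± 1.3 at 8 weeks. The age clock genes averaged 10.6% ± 0.328 against 8.91% ± 0.647 and the developmental factors 5.74% ± 0.172 against 5.32% ± 0.137, each with an exact permutation p of 0.0286 and 0.0762 adjusted over 136 list tests, so neither passed. The cluster mean was 6.83% ± 0.0281 and 6.79% ± 0.0331 (exact permutation p = 0.143, 0.204 adjusted), and the share of clusters that gained 0.153% ± 0.0715 and 0.0808% ± 0.0182 (exact permutation p = 0.114, 0.143 adjusted).

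In TG thymi the same ages differed widely: 1840 clusters rose and 15 fell between 8 and 24 weeks, and 887 gene windows rose and 23 fell. Marveld2, a tight junction gene (chromosome 13, 100616471 to 100617971, 16 sites), stood at 79.8% ± 22.9 against 4.93% ± 3.33 (adjusted p = 0.00865), Lgals3 at 88.2% ± 16.6 against 15.4% ± 4.82 (adjusted p = 0.0174), Fam83f at 90.6% ± 9.11 against 21.6% ± 7.93 (adjusted p = 0.00504) and Btbd3 at 68.3% ± 6.66 against 9.96% ± 6.25 (adjusted p = 0.00504). Naaladl2, Hebp2, Sstr4, Rln1, Sema4b and Cdx1, an intestinal homeobox gene, were the other largest rises. Pgpep1 (28.7% ± 7.53 against 81.7% ± 11.8), Slpi, Cend1, Scamp3 and Mgst2 were the largest falls. Of 116 developmental factors 43 rose (64 adjusted over the list alone), of 30 Hox genes 10 (18), of 36 Wnt, BMP and hedgehog genes 10 (14) and of 18 age clock genes 6 (8), none with a fall, where the number in parentheses is adjusted over the list alone. Camera called these 4 lists with an estimated correlation, with adjusted p from 0.01 to 0.0206. Irx1 stood at 68.1% ± 6.2 against 15% ± 4.22, Sox2 at 38.3% ± 18 against 5.33% ± 3.75, Bmp2 at 62.5% ± 2.38 against 11.1% ± 1.64 and Hoxa2 at 38.9% ± 15.3 against 5.07% ± 3.6. Meis1, Tlx3, Hoxa11 and Nkx2-1 rose among the T-ALL oncogenes, Peg12, Nap1l5 and Rasgrf1 among the imprinted genes, and Pcdhga9 and Pcdhga11 among the protocadherins. Ebf1 and Fcgr3 rose and Cebpe fell among the markers of other blood cells.

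The cluster mean of TG thymi was 8.84% ± 0.357, 10.8% ± 0.538 and 13.5% ± 0.437 at 8, 16 and 24 weeks. Over the 12 TG libraries it followed age with Pearson r = 0.975 and Spearman rho = 0.946 (permutation p = 8e-05 for each, 0.00016 adjusted over 4 relations). Leaving out any 2 libraries of the youngest or oldest group left r between 0.965 and 0.982. Over the 12 WT libraries r was 0.301 (permutation p = 0.349, also adjusted) and rho 0.43 (permutation p = 0.171, also adjusted), with r from 0.0863 to 0.431 without 2 libraries. The number of clusters that rose from 8 to 24 weeks was 1157 and 1220 without TG 24-week replicates 3 and 4 and 1163 without TG 8-week replicate 4. With an offset of 0.001 it was 678, with 8 falls.

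Whether age acted differently in the 2 genotypes was tested as a difference of differences. It was positive at 852 clusters and negative at 11, and at gene windows positive at 434 and negative at 19. Irx1 went from 15% ± 4.22 to 68.1% ± 6.2 in TG and from 2.51% ± 1.34 to 4.11% ± 2.49 in WT (adjusted p = 0.0106). Bmp2 went from 11.1% ± 1.64 to 62.5% ± 2.38 and from 2.46% ± 1.06 to 1.91% ± 0.725 (adjusted p = 0.000657). Marveld2, Lgals3, Rln1, Fam83f and Sema4b led the positive differences and Pgpep1, Slpi, Alox12b, Minar2 and Srsf1 the negative ones. Of 116 developmental factors 18 were higher (45 adjusted over the list alone), of 30 Hox genes 4 (10), of 36 Wnt, BMP and hedgehog genes 4 (13), of 18 age clock genes 2 (5) and of 22 imprinted genes 2 (4). Camera called these 5 lists with an estimated correlation (adjusted p from 0.000457 to 0.0117). The share of clusters that gained rose by 11.6 percentage points more in TG than in WT (exact permutation p = 0.0286, 0.0408 adjusted). The cluster count depended on the scale, with 20 positive and 1 negative at an offset of 0.001 and 1814 positive on untransformed values. Without TG 24-week replicate 1 the negative differences numbered 17.

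Lmo2 T-ALL was set against TG thymi of 24 weeks, the oldest premalignant group. No cluster was called by limma in either direction, with 1528 at an unadjusted p under 0.05, although cluster differences ran from -0.593 to 0.503 in beta. At gene windows 1 was called, Dnajc12 (chromosome 10, 63381443 to 63382943, 13 sites), with 0.313% ± 0.0729 against 23.9% ± 10.8 (adjusted p = 0.0135). This call was lost on untransformed values and with the replicate number as a block, where the difference stayed -23.6 percentage points, and without T-ALL replicate 1, 2 or 4 (-23.6 each) or TG replicate 4 (-24.7). Developmental factors averaged 17.9% ± 7.04 against 24.3% ± 1.89, Hox genes 19% ± 5.18 against 27.7% ± 1.06 (exact permutation p = 0.0286, 0.0762 adjusted) and age clock genes 26.3% ± 3.89 against 32.8% ± 0.932. When adjusted over the list alone, 6 Hox genes were lower, and camera gave adjusted p = 0.461 with an estimated correlation for the Hox list and 0.659 for the developmental factors. The B cell markers averaged 36.4% ± 3.12 against 47.8% ± 11.1 and the T lineage genes 17.2% ± 0.205 against 16.1% ± 1.87. The cluster mean was 11.1% ± 1.97 in T-ALL and 13.5% ± 0.437 in TG thymi (exact permutation p = 0.143, 0.204 adjusted), with T-ALL replicates 1, 2 and 4 at 10.2%, 10.6% and 9.72% and replicate 3 above every TG library. The share of clusters that gained was 10.1% ± 4.6 and 15.4% ± 0.962 (exact permutation p = 0.143, 0.159 adjusted). These T-ALL libraries were from spleen, had no age given and listed more sites than the TG thymus libraries. Leukemia, tissue, age and library set therefore cannot be told apart here. A fit of all 40 samples called 1 cluster higher and 69 lower, and without TG 24-week replicate 2 there was 1 lower.

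The leukemias of the 2 models were compared as differences from their own WT thymi of 8 weeks. Lmo2 T-ALL from spleen was set against thymus libraries that listed fewer sites, and Pten KO T-ALL from thymus against thymus. Tissue, library set and the unknown age of the leukemias therefore cannot be told apart from the model here. The change in Lmo2 T-ALL exceeded that in Pten KO T-ALL at 318 clusters and lay below it at 66, and at gene windows 207 were higher and 48 lower. Mchr1 went from 6.94% ± 4.81 to 85.4% ± 11 in Lmo2 T-ALL and from 5.66% ± 3.12 to 5.7% ± 4.76 in Pten KO T-ALL (adjusted p = 0.00167). Gal went from 4.87% ± 3.02 to 80.8% ± 5.42 and from 6.07% ± 3.77 to 7.36% ± 7.01 (adjusted p = 0.00133). Cbfa2t3 stood at 0.779% ± 0.576 in Lmo2 T-ALL and 60.4% ± 14.9 in Pten KO T-ALL (adjusted p = 0.000278), and Kit at 0.833% ± 1.3 and 19% ± 7.5 (adjusted p = 0.00559). Camk2a, Rsph1, Slc15a1, Npffr1 and Cdx1 were further positive differences, and C2cd4d, Cd59a, Scamp3 and Ripor2 negative ones. Hoxc5 and Hoxd13 were higher and Hoxa5 lower among 30 Hox genes, Pou3f3 and Lhx1 higher among 116 developmental factors, and Wnt10a and Bmp8a higher among 36 Wnt, BMP and hedgehog genes. Fcgr3 was higher among 7 myeloid and Pdgfrb lower among 7 stromal windows. Open sea changed by -7.83 percentage points in Pten KO T-ALL and -0.407 in Lmo2 T-ALL, a difference with an exact permutation p of 0.0286 and 0.0536 adjusted. The share of clusters that gained was 6.44 percentage points further above its WT in Lmo2 T-ALL than in Pten KO T-ALL (exact permutation p = 0.0286, 0.0408 adjusted), and 4.24 without Lmo2 T-ALL replicate 3. The WT groups came from libraries of different breadth, with 2 clusters called between them and 2336 at an unadjusted p under 0.05. Their cluster means were 6.79% in the Lmo2 and 5.85% in the Pten model. Between the leukemias, an offset of 0.001 left 58 clusters higher and 19 lower.

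Clusters chosen in one model were measured in the libraries of the other. The 914 clusters higher in Pten KO T-ALL than in Pten WT thymi stood at 25.0% ± 2.66, 36.4% ± 3.86 and 49.9% ± 1.36 in TG thymi of 8, 16 and 24 weeks and at 9.96% ± 0.162, 10.2% ± 0.405 and 10.3% ± 0.0786 in WT. TG against WT at each age, 24 against 8 weeks in TG, the difference of 0.334 percentage points between 24 and 8 weeks in WT, and the difference between these last 2 each had an exact permutation p of 0.0286, also after adjustment over 8 tests. All 8 tests stood at this smallest p, so adjustment left it unchanged and it does not reflect the size of a difference. Over the 12 TG libraries the level followed age with Pearson r = 0.971 and Spearman rho = 0.946 (permutation p = 4e-05 for each, 0.00016 adjusted), with r from 0.959 to 0.976 without 2 libraries. The ages did not overlap in this level or in the cluster mean, so this permutation p and the 8e-05 given there differ only by the random draw. Over the 12 WT libraries r was 0.523 (permutation p = 0.0793, 0.106 adjusted) and rho 0.591 (permutation p = 0.0521, 0.0694 adjusted), with r from 0.337 to 0.597. The 2732 clusters higher in Lmo2 T-ALL than in Lmo2 WT thymi stood at 6.86% ± 0.069 in Pten WT thymi, 7.29% ± 0.222 in KO thymi and 17.1% ± 1.57 in Pten KO T-ALL (exact permutation p = 0.0286 for both steps, before and after adjustment). The first of these steps was only 0.422 percentage points, and no single cluster was called between Pten KO and WT thymi.

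**Figure D4:**
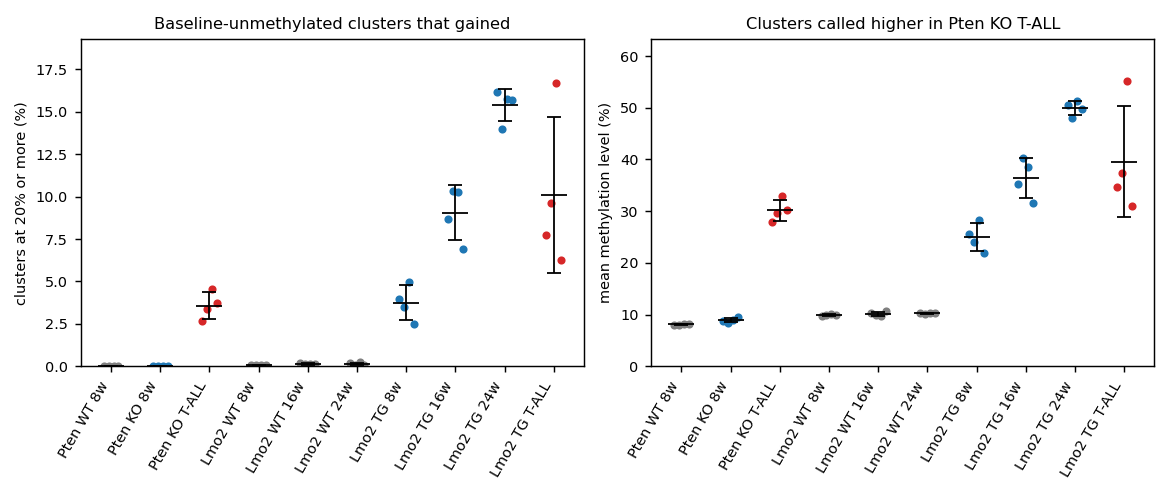
The left panel shows the share in percent of baseline-unmethylated clusters at a level of 20% or more in each library, and the right panel the mean level in percent of the 914 clusters higher in Pten KO T-ALL than in Pten WT thymi, which for those 2 groups are the libraries they were chosen on. Points are libraries, the long tick is the mean and bars are SD (n = 4), and TG thymi of 24 weeks averaged 15.4% and 49.9%.

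Overlaps were counted between comparisons that share no library. Of the 914 and 2732 clusters higher in the 2 leukemias against their WT, 767 were shared, where independent lists would share 147, and the differences correlated across clusters with r = 0.668 (covariance 52.0 squared percentage points), clusters not being independent replicates. Of the 793 clusters that rose from KO thymi to Pten KO T-ALL and the 1840 that rose with age in TG thymi, 477 were shared against 86.0 for independent lists. Of 2732 clusters higher in Lmo2 T-ALL than in WT thymi of 8 weeks, 2503 were also higher in TG than in WT thymi of 24 weeks, against 559 for independent lists. Between Pten KO T-ALL against KO thymi and Lmo2 T-ALL against TG thymi of 24 weeks the differences correlated with r = -0.395, with no call in the second comparison to share.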

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

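The tests on bisulfite conversion, library breadth, library set, the offset between library sets, the splits of the samples and the spread of the differences of differences were chosen after the results were seen; those on other cell populations and normal cells in the spleen were written before theirs.

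In 3 cases a library stood apart from the other 3 of its group, where chance marks about 1 group in 20 and 60 were tested. The cluster mean of TG thymus replicate 2 at 24 weeks was 12.8%, below the other 3. The share of baseline-unmethylated clusters that gained was 0.0538% in Lmo2 WT replicate 1 of 8 weeks. The mean over clusters gained in Lmo2 T-ALL was 8.30% in Lmo2 WT replicate 3 of 8 weeks. Effects also differed between groups: age acted differently by genotype at 852 clusters upward and 11 downward, and the leukemias of the 2 models differed at 318 clusters upward and 66 downward.

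The gain of cluster methylation with age in TG thymi, for which age itself is the hypothesis the design names, was weighed against 3 other explanations. Incomplete bisulfite conversion would raise housekeeping windows too, yet their median difference between TG and WT at 24 weeks was -0.271 percentage points. Library breadth would leave no difference between libraries with like numbers of listed sites, yet the smallest difference in cluster mean between a TG library of 24 weeks and the TG library of 8 weeks nearest to it in breadth was 4.20 percentage points. Another cell population in the transgenic thymus stays open, since the most windows measured for any list of marker genes of other cells was 7, too few to decide. At 24 weeks the lists averaged 47.8% in TG against 27.3% in WT for B cells, 23.2% against 12.6% for erythroid cells and megakaryocytes, 10.5% against 1.63% for effector cells and 61.1% against 55.4% for myeloid cells, each with an exact permutation p of 0.0286 and 0.0762 adjusted, while stromal markers averaged 20.7% against 18.7% (exact permutation p = 0.171, 0.328 adjusted) and T lineage genes 16.1% against 15.8% (exact permutation p = 0.83, 0.86 adjusted).

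The absence of higher clusters in Lmo2 T-ALL against TG thymi of 24 weeks was weighed against 2 explanations. For the library set, the difference in cluster mean was -1.37 percentage points after each group was set against the WT group of like breadth, within the T-ALL SD of 1.97, so it cannot be told apart. For normal cells in the spleen samples, baseline-unmethylated clusters at 90% or more were counted. T-ALL replicates 1 to 4 had 12, 11, 32 and 4, and TG replicates 1 to 4 of 24 weeks 53, 26, 35 and 25. The prediction asked for few such clusters in every T-ALL library, or for many in every one. The counts met neither bound, so this is open too. A difference between spleen and thymus, or in age, is confounded with leukemia and was not tested.

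Open sea methylation was lower in Pten KO T-ALL than in its WT thymi, with a difference between the models of 7.42 percentage points. An offset between the library sets is argued against, since the WT groups differed by 1.82 percentage points and the combined SD of the leukemias was 1.49. The biological difference that the design names is the model itself, together with spleen against thymus for the leukemias, whose ages are not given. These cannot be separated here.

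Other splits of the same samples were counted for each comparison of clusters. For Pten KO T-ALL against KO thymi (918 calls), TG against WT thymi at 8, 16 and 24 weeks (923, 2415 and 3519 calls) and TG thymi of 24 against 8 weeks (1855 calls), only the real split, 1 of 35, gave as many calls. The highest other gave 0, or 1 for the 8-week comparison, which argues against chance. Chance is not excluded, since 1 of 35 is the smallest share these splits can give. For Pten KO against WT thymi, WT thymi of 24 against 8 weeks and Lmo2 T-ALL against TG thymi of 24 weeks, which had 0 calls, all 35 of 35 splits gave as many, with 0, 0 and 2 as the highest other. With 0 real calls the 35 of 35 was fixed in advance and decides nothing. For the difference by age and genotype 3 of 100 drawn splits gave as many as the real 863, the highest other 2816, and for that between the leukemias 4 of 100 gave as many as the real 384, the highest other 1997. These regroupings of 4 groups also undo the differences by age, genotype and model, so they do not test a difference of differences, and why some gave several times the real calls was not tested. By age and genotype the cluster mean differed by 4.58 percentage points, 4.46 to 4.79 with each replicate left out, against a combined SD of 0.566 for the 4 groups, which argues against chance. Between the leukemias it differed by 2.59 against a combined SD of 2, and by 1.62 without Lmo2 T-ALL replicate 3. That SD includes replicate 3, so it is no measure for the 1.62. The exact permutation p of the 2.59 was 0.0286 and 0.0536 adjusted, so chance stays open there.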

How the results depend on the processing

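The alternatives that use clusters of at least 5 listed CpG per 100 bases and both gene ends pooled were chosen after seeing the data. Not run were at least 10 and at least 3 sites per island (clusters already hold 10 or more), chromosomes X and Y (only 19 autosomes are listed) and the gene 5′ end alone (no strand). Depth is unknown and limits every value. No difference that passed its test changed sign under the alternatives run. Differences that did not pass changed sign when a replicate was left out in open sea for TG against WT at 16 weeks (-0.267 to 0.173 points) and 24 weeks (-0.375 to 0.66), TG 24 against 8 weeks (-1.03 to 0.0067), Lmo2 T-ALL (-0.997 to 0.0379) and age by genotype (-0.958 to 0.0765), and in shores for Pten KO against WT (-0.0066 to 0.061) and WT 24 against 8 weeks (-0.0342 to 0.0303). With sites in all 40 samples the first 2 of these in open sea and both in shores changed sign, and the Pten window, near 0% throughout, did so in all 10 comparisons but TG against WT at 16 and 24 weeks when replicates were left out. With sites present in all 40 samples, all 20 cluster counts stayed within 1.5 times. Below, counts are higher/lower, and the cause was not tested except that 20-point differences and 20-site clusters call fewer by construction.

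With an offset of 0.001, Pten KO T-ALL had 76 lower, TG against WT 335 and 16 at 8 weeks and 39 lower at 16 weeks, TG 24 against 8 weeks 678 and 8, age by genotype 20 and 1, and the models 58 and 19. On untransformed values Pten KO T-ALL had 476 and 82, TG 24 against 8 weeks 9 lower, and age by genotype 1814 higher. At a difference of 20 points there were 376 and 41 for Pten KO T-ALL, 348 and 1103 higher for TG against WT at 8 and 16 weeks, 29 lower at 24 weeks, 9 lower for TG 24 against 8 weeks and 180 higher between models. Clusters of at least 20 sites gave 340 and 4 for Pten KO T-ALL, 360 and 15, 982 and 13, and 1487 and 9 for TG against WT at 8, 16 and 24 weeks, 1046 and 1 for TG 24 against 8 weeks, 1 lower for age by genotype, and 135 and 21 between models. Denser clusters gave 54 lower for Pten KO T-ALL, 8 for TG 24 against 8 weeks and 5 for age by genotype. One fit of all 40 samples gave 30 lower for TG 24 against 8 weeks, 1 and 69 for Lmo2 T-ALL, and 18 lower for age by genotype.

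Correlations of same-numbered deviations lay between -0.016 and 0.044, under the limit of 0.1 set for a pairing of samples by replicate number. Only in TG thymi of 24 against 8 weeks did every sample correlate best with its own number, with a mean of 0.03 against -0.01 for other numbers. A weak pairing is not excluded there. With the replicate number as a block, Pten KO T-ALL had 485 higher and 62 lower, TG against WT at 8 weeks 30 lower and TG 24 against 8 weeks 9 lower, and the other 16 cluster counts stayed within 1.5 times.

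Leaving out each replicate in turn gave 70 to 103 lower in Pten KO T-ALL, 35 to 55 lower in TG at 8 weeks, 1157 to 1679 higher for TG 24 against 8 weeks, 0 to 1 lower in Lmo2 T-ALL and 9 to 17 lower for age by genotype. The age by genotype difference over the clusters gained in Pten KO T-ALL ran from 23.6 to 25.7 percentage points, and the difference between the leukemias in the share that gained from 4.24, without Lmo2 T-ALL replicate 3, to 7.71. The share that gained differed by 0.0361 points between Pten KO and WT thymi with sites in all 40 samples, and by 0.0269 between WT thymi of 24 and 8 weeks at a gain of 30%, both then at an exact p under 0.05 unadjusted. In both, the reference samples are among the WT samples of 8 weeks on which the clusters were chosen, which lowers their share and favours such a difference. Of the named windows 465 of the leave-one-out fits, 61 under the block, 39 on untransformed values and 13 with both ends pooled lost the call in the same direction, and 2159, 203, 225 and 251 kept their side.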

Other observations

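The tests below were written before their results were seen. Clusters that gained in Lmo2 leukemia were asked whether they sit at a higher level than in TG thymi of 24 weeks, as outgrowth of single clones might give. The mean level of gained clusters was 33.0%, 33.7%, 43.5% and 31.9% in the T-ALL libraries and 40.8%, 39.2%, 40.5% and 39.3% in the TG libraries, so the groups overlapped (exact permutation p = 0.143) and the prediction was not met.

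CpG density was tested as a possible correlate of the gain with age. Across baseline-unmethylated clusters, which are not independent replicates, the Spearman correlation between density and the rise from TG 8 to 24 weeks was -0.0424, short of the bound of -0.1. The mean rise was 4.85, 4.18, 4.25 and 3.99 percentage points from the least to the most dense of 4 equal groups of clusters.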
